A study of Mus musculus with 8 samples.

How the data were processed

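RNA sequencing was analysed in 8 libraries of macrophages sorted from mouse pancreatic islets as CD11b and F4/80 double-positive cells. Male C57BL/6J mice received either chow or a high-fat diet (HFD) for 8 weeks from 8 weeks of age and were 16 weeks old at collection, per the labels' protocols. Chow held 8% fat, 21% protein and 71% carbohydrate at 10.88 kJ/g. HFD held 45% fat, 20% protein and 35% carbohydrate at 19.67 kJ/g. Each diet had 4 libraries, and each library was made from islets pooled from 2 mice, so a library and not a mouse is the unit of replication. RNA was extracted on columns, and 500 pg was amplified to cDNA with the Ovation RNA-Seq System V2. No molecular identifiers or strand information were stated for this kit in the sources used here, so counts are not independent molecules and antisense transcripts cannot be told apart.

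Reads were checked with FastQC, trimmed with Trim Galore and aligned with STAR to the GRCm38 mouse genome, per the submitters' processing notes. Their versions, the program that counted reads per gene, the annotation release and any filter are not given in the sources used here. The deposited table holds expected counts, not scaled between libraries, for 48440 Ensembl genes. Between 939 and 1115 values per library were not whole numbers, 7.66% to 8.32% of the values above 0. All values were rounded to whole numbers before any test. Fractional values point to reads divided between features, so members of near-identical gene families such as ribosomal proteins and their pseudogenes, the trypsin and elastase enzymes, and Ins1 with Ins2 are reported as uncertain. Gene symbols came from the GENCODE M21 annotation of the same assembly, in which 48058 of the 48440 identifiers were found; for the other 382 the symbol in the table or the identifier was used. Coordinates are 1-based on GRCm38.

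Library totals ranged from 4288665 to 6391247 counts. A count of 0 in a single library allows a level of up to 0.468 to 0.708 CPM (counts scaled by the library's effective total), taken as 3 counts of the scaled total; such floors cover counting error only. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom over the 28 pairs was 36.3. Replicate numbers run from 1 to 4 in chow and from 5 to 8 in HFD, so they pair no libraries.

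Genes were tested with the quasi-likelihood test of edgeR (version 4.0.16) with TMM scaling, the filterByExpr filter with the diet groups, a robust fit with diet as the only term, and Benjamini-Hochberg adjustment at 0.05, all two-sided. The filter kept 10129 genes. Levels are given as TMM-scaled CPM, mean ± SD over 4 libraries, and log2 fold changes are HFD over chow with standard errors (SE) from the same fit. The 35 pathway lists and 16 cell type lists were fixed from the design, and pathway and cell type lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of each kind. For each list the number of called genes is given adjusted over all genes and adjusted over the list alone. Cell type transcripts were also summed per library on all genes, and the mean log2 of the sum plus 1 CPM was compared by a two-sided exact permutation test over the 70 arrangements, whose smallest p is 0.0286. Library measures were compared with the same exact test. Of the 1231 list symbols, 7 were not found under the names used.

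Genes to be named were set by a rule: up to 12 called genes per direction and, with fewer than 5 called genes, the 10 genes with the smallest p, named as not past the threshold; a panel of 20 macrophage, lipid, cytokine, hormone and enzyme genes; and up to 4 genes per described list, those with the smallest p. A gene named outside this rule is said to be chosen after its values were seen. Tests, lists, this rule and the main alternatives were chosen before the data were examined. Alternatives comprised other scalings (RLE, upper quartile, library totals), no filter or at least 5 CPM in at least 4 libraries, each library left out in turn, a covariate for acinar or pan-endocrine transcripts, a surrogate variable from sva (version 3.50.0), limma-voom (limma version 3.58.1) with sample quality weights, DESeq2 (version 1.42.0), a fit that was not robust, other thresholds, removal of mitochondrial, haemoglobin, hormone and acinar genes, camera with an estimated correlation, and fry. An exact permutation test on list means per library, a covariate for stellate and fibroblast transcripts, removal of those transcripts from the pathway lists, and cell type lists with at least 3 tested genes were added after seeing the data. The analysis ran in R (version 4.3.3).

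The edgeR and camera steps were tested on simulated data drawn from the means and spread of these libraries, with 10129 genes, 200 of them changed, in 5 simulations of the HFD versus chow comparison. Of simulated 2-fold changes 3.8% were called, of 4-fold changes 33.6% and of 8-fold changes 49.3%. Among the upper 50% of genes by expression these shares were 7.4%, 56.9% and 73.6%. Among unchanged genes 4.19% had an unadjusted p under 0.05, and calls comprised on average 1.8 false ones of 40.4. A list shifted 1.5-fold was called in 5 of 5 simulations, and with no list shifted 0.2 lists were called per simulation on average. Genes were drawn independently of each other here. In the real data the estimated correlation reached 0.36 within a called list, alternatively activated and perivascular macrophages. The simulations therefore cannot tell how often camera calls lists of correlated genes by chance.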

Results

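The data comprised expected counts per gene for macrophages sorted from the pancreatic islets of male C57BL/6J mice kept for 8 weeks on chow or on a high-fat diet (HFD) with 45% fat. There were 4 libraries per diet, each from islets pooled from 2 mice. Library totals were 4670061, 6391247, 5208931 and 4288665 counts for chow replicates 1 to 4, and 4698206, 5917920, 4532503 and 5080074 counts for HFD replicates 5 to 8. Transcripts of the sort markers were abundant in both diets. Adgre1, which encodes F4/80, was at 506 ± 78.4 CPM in chow and 419 ± 74.2 CPM in HFD (SD, n = 4). Itgam, which encodes CD11b, was at 312 ± 71.3 and 337 ± 98.3 CPM. The macrophage receptor gene Csf1r was at 916 ± 99.3 and 863 ± 117 CPM, and the lysosomal marker Cd68 at 366 ± 90.7 and 354 ± 45.9 CPM. None of these 4 genes passed the threshold (edgeR adjusted p = 0.99 each), with log2 fold changes of -0.27 (SE 0.19), 0.11 (SE 0.24), -0.09 (SE 0.15) and -0.05 (SE 0.21).

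The comparison of HFD with chow asked which transcripts of islet macrophages differ after 8 weeks of the diet. As groups, genes of the lipid-associated macrophage list were higher in HFD and genes of MHC class II antigen presentation were lower with camera at its preset correlation (adjusted p = 3.9e-06 and 0.00095). Neither passed with an estimated correlation (adjusted p = 0.37 and 0.61) or with fry (adjusted p = 0.19 and 0.36). The single genes with the smallest p were Igf1, a growth factor, which was at 155 ± 109 CPM in HFD against 18.4 ± 4.13 CPM in chow, and Itgb8, an integrin subunit, at 135 ± 22.6 against 305 ± 33.0 CPM (SD, n = 4). No single gene passed the threshold: edgeR called 0 of 10129 genes, with 542 at an unadjusted p under 0.05 where 506 would be expected from uniform p-values and the 34 other splits of the libraries gave 319 to 502, while DESeq2 called 92 genes and limma-voom with quality weights called 1, Cdk6.

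The 10 genes with the smallest p in edgeR, none past the threshold, were Igf1, Itgb8, Cdk6, Cd93, Il1b, Gm38357, Cd81, Fbxw11, Rcc1l and Cdk13. Igf1 (chromosome 10, 87858265 to 87937042) had a log2 fold change of 3.07 (SE 0.51, adjusted p = 0.084) and was above every chow library in 4 of 4 HFD libraries, although its levels there ran from 31.9 CPM in HFD replicate 8 to 293 CPM in HFD replicate 5. With the stellate and fibroblast covariate, added after seeing the data, its log2 fold change was 0.54 (SE 0.56, adjusted p = 0.999), the lowest of a range of 0.54 to 3.403 over the alternatives. Cd93 (chromosome 2, 148436640 to 148443563), a complement-related surface receptor, was at 66.8 ± 13.9 CPM in chow and 175 ± 48.4 CPM in HFD, with a log2 fold change of 1.39 (SE 0.31, adjusted p = 0.58). Itgb8 (chromosome 12, 119158022 to 119238802) had a log2 fold change of -1.18 (SE 0.23, adjusted p = 0.22). Cdk6 (chromosome 5, 3341485 to 3531008), a cyclin-dependent kinase, was at 1617 ± 160 CPM in chow and 1027 ± 46.6 CPM in HFD, a log2 fold change of -0.66 (SE 0.13, adjusted p = 0.24). Il1b (chromosome 2, 129364570 to 129371139), which encodes the cytokine interleukin-1 beta, was at 207 ± 33.5 and 72.9 ± 38.8 CPM, a log2 fold change of -1.51 (SE 0.35, adjusted p = 0.58). Cd81, a tetraspanin, was at 546 ± 71.3 CPM in chow and 311 ± 59.6 CPM in HFD. Fbxw11 had a log2 fold change of -1.29 (SE 0.31) and Cdk13 one of -1.21 (SE 0.30). Rcc1l had 3 counts over the chow libraries and 252 over the HFD libraries, a ratio of 81.6 in CPM with a counting interval of 27.6 to 398. Gm38357, with a log2 fold change of 2.66 (SE 0.62), lies within Noct on the same strand, so its reads cannot be assigned with certainty. DESeq2 called all 10 of these genes. Without HFD replicate 8, edgeR called 11 genes, among them Igf1, Mrc1 and the collagen genes Col1a1, Col1a2 and Col3a1, the collagens being named after their values were seen.

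**Figure D1:**
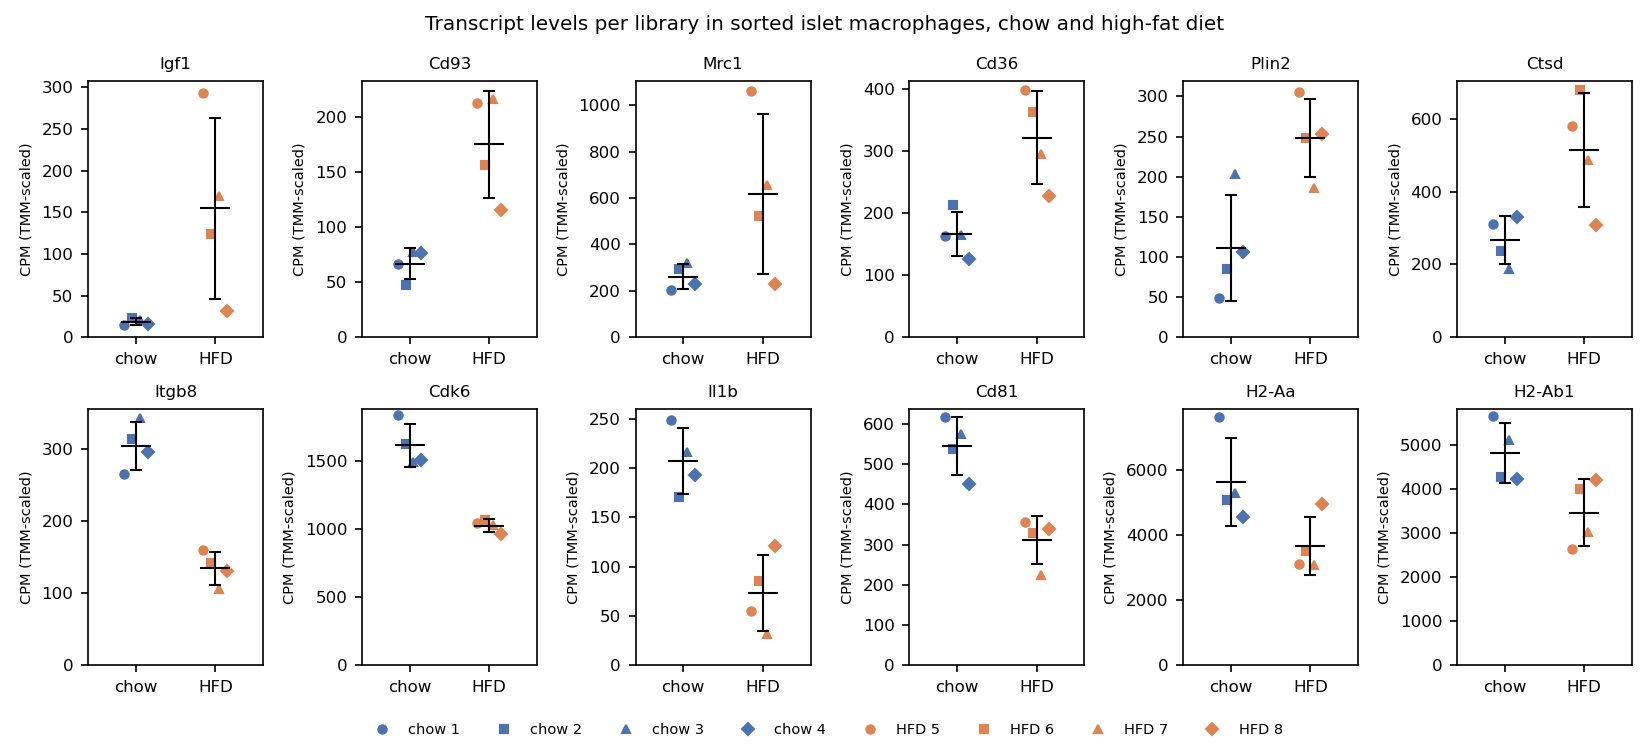
Levels of 12 genes in each library, in TMM-scaled CPM on axes that start at 0; points are libraries, horizontal bars the mean and whiskers the SD of 4 libraries per diet. Cdk6 sits at 1027 ± 46.6 CPM in HFD and 1617 ± 160 CPM in chow, whereas Igf1 and Mrc1 of HFD replicate 8 sit near the chow libraries at 31.9 and 231 CPM.

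Among the 20 panel genes, 4 were called when adjusted over the list alone and 0 when adjusted over all genes tested. These 4 were Il1b, Cd36, Mrc1 and Plin2. Cd36, a fatty acid translocase, was at 167 ± 35.4 CPM in chow and 322 ± 75.3 CPM in HFD, with the groups not overlapping. Plin2, a lipid droplet coat protein gene, was at 111 ± 65.9 and 248 ± 49.0 CPM. Mrc1, the mannose receptor, was at 261 ± 55.3 and 617 ± 344 CPM, with 231 CPM in HFD replicate 8. Its log2 fold change of 1.24 (SE 0.32) turned to -0.40 (SE 0.33) with the stellate and fibroblast covariate. The lipoprotein lipase gene Lpl was at 201 ± 40.8 and 265 ± 48.3 CPM, and Itgax, which encodes CD11c, at 349 ± 54.8 and 408 ± 36.5 CPM. Apoe was at 1328 ± 213 CPM in chow and 1043 ± 189 CPM in HFD. Cx3cr1, Cd9, Trem2, Tnf and Pdgfb had edgeR adjusted p-values of 0.99, with SEs of 0.20 to 1.13 on the log2 scale; Trem2 was at 33.7 ± 15.9 and 39.5 ± 28.8 CPM, Tnf at 3.84 ± 1.36 and 8.07 ± 4.25 CPM, and Pdgfb at 33.3 ± 4.82 and 21.6 ± 9.04 CPM.

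Of the 35 pathway lists, 7 passed the camera threshold, 5 higher and 2 lower in HFD. All 7 calls were lost with an estimated correlation between genes, where the adjusted p-values were 0.37 to 0.64. The lipid-associated macrophage list, with genes of lipid handling and lysosomes, rose as a group (camera adjusted p = 3.9e-06; adjusted p = 0.37 with an estimated correlation). Of its 25 tested genes 19 were higher and 6 lower, with a median log2 fold change of 0.47. Adjusted over the list alone 5 genes were higher, Igf1, Cd36, Ctsd, Plin2 and Lipa, and 0 were called over all genes. Ctsd, a lysosomal protease gene that overlaps the model Gm49369 on the same strand, was at 266 ± 66.4 CPM in chow and 515 ± 157 CPM in HFD. The list also holds Apoe, with a log2 fold change of -0.35 (SE 0.16). The mean log2 CPM of the list was 6.44, 6.37 and 6.53 in HFD replicates 5, 6 and 7 and 5.41 in HFD replicate 8, against 4.97 to 5.49 in chow. Stellate and fibroblast transcripts were at 512, 309 and 256 CPM in HFD replicates 5, 6 and 7 and 106 CPM in HFD replicate 8, and with that list as a covariate the median was 0.03 (adjusted p = 0.84, the highest of a range of 1.1e-09 to 0.84 over the alternatives).

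The list of alternatively activated and perivascular tissue macrophages also rose (camera adjusted p = 0.00095; adjusted p = 0.61 with an estimated correlation). Of its 12 tested genes 11 were higher and 1 lower, with a median log2 fold change of 1.40. Only Mrc1 was called when adjusted over the list alone, and 0 genes over all genes. Igfbp4 was at 9.23 ± 3.59 CPM in chow and 29.9 ± 18.1 CPM in HFD, and the carbonyl reductase gene Cbr2 at 2.89 ± 3.58 and 22.0 ± 23.1 CPM. Cd209a, a lectin gene, was at 1.70 ± 2.18 and 9.67 ± 9.53 CPM. Both Cbr2 and Cd209a had 0 CPM in HFD replicate 8, where a floor of 0.603 CPM applies. The mean log2 CPM of this list was 5.47, 3.89 and 4.56 in HFD replicates 5, 6 and 7, 1.80 in HFD replicate 8, and 1.97 to 3.41 in chow. Without HFD replicate 5 the adjusted p was 0.18, within a range of 1.5e-10 to 0.18 over the 8 libraries left out in turn. With the stellate and fibroblast covariate the list turned lower in HFD, with a median of -2.27 (SD over genes 3.54, adjusted p = 0.18), and over all alternatives the adjusted p ranged from 1.5e-10 to 0.64.

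Genes of MHC class II antigen presentation fell as a group (camera adjusted p = 0.00095; adjusted p = 0.61 with an estimated correlation), with 9 of 11 tested genes lower, 2 higher and a median log2 fold change of -0.46. Adjusted over the list alone 3 genes were lower, H2-Aa, H2-Ab1 and Cd74, and 0 were called over all genes. H2-Aa (chromosome 17, 34282744 to 34287823), the class II alpha chain, was at 5638 ± 1363 CPM in chow and 3664 ± 891 CPM in HFD. Its partner H2-Ab1 was at 4818 ± 693 and 3462 ± 760 CPM, with every HFD library below every chow library. The invariant chain gene Cd74 was at 13770 ± 1503 and 10150 ± 3091 CPM, and H2-DMb1, a peptide-loading gene, at 95.1 ± 24.6 and 45.5 ± 22.4 CPM. With the stellate and fibroblast covariate the median was -0.10 (adjusted p = 0.98, within a range of 1.2e-06 to 0.98 over the alternatives) and the log2 fold change of Cd74 turned from -0.44 to 0.20. Summed transcripts of the dendritic cell list were at 932 ± 106 CPM in chow and 772 ± 67.7 CPM in HFD. Those of the B cell list were at 358 ± 92.9 and 262 ± 55.1 CPM. The mean log2 CPM of the tested genes went the other way, from 3.94 to 4.29 for the dendritic cell list and from 3.01 to 3.27 for the B cell list. Their median log2 fold changes were -0.13 for the dendritic cell list, with 7 of 12 tested genes lower, and -0.49 for the B cell list, with 3 of 5 lower. Camera gave both lists the direction lower in HFD but called neither (adjusted p = 0.90 each). The dendritic cell list shares Bst2 with the interferon-stimulated list, so its sum is not particular to these cells. HFD replicate 5 had the lowest dendritic cell sum, 672 CPM, and the lowest class II mean. Chow replicate 1 had the highest B cell sum, 489.5 CPM, and the highest class II mean. In chow replicates 1 to 4 the B cell sums, 489.5, 357, 301.5 and 284.4 CPM, fell in the order of the class II means. Those means were 8.968, 8.777, 8.555 and 8.373. Chow replicates 1 and 2 also had the highest dendritic cell sums, 1057 and 973 CPM. Other comparisons between libraries went against such a link. HFD replicate 8 had the lowest B cell sum, 214.5 CPM, with the highest class II mean of the HFD libraries, 8.547. Chow replicate 3 had a lower dendritic cell sum than chow replicate 4, 813 against 886 CPM, with a higher class II mean, 8.555 against 8.373. H2 genes resemble each other, so their counts are uncertain.

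The list for lipid uptake and lipid droplets rose close to the threshold (camera adjusted p = 0.047; adjusted p = 0.37 with an estimated correlation), with 12 of 17 tested genes higher and a median log2 fold change of 0.70. Adjusted over the list alone 3 genes were higher, Cd36, Plin2 and Slc27a1, and 1 was lower, Acsl1, against 0 over all genes. Slc27a1, a fatty acid transport protein gene, was at 2.22 ± 1.71 CPM in chow and 25.6 ± 21.9 CPM in HFD. Acsl1, a long-chain acyl-CoA synthetase gene, was at 219 ± 72.9 and 106 ± 16.9 CPM. This call ended without HFD replicate 5 (adjusted p = 0.11) and without HFD replicate 7 (0.066), within a range of 0.0016 to 0.11 over the 8 libraries left out in turn. It also ended with the filter at 5 CPM (0.12), the pan-endocrine covariate (0.11), the surrogate variable (0.13), limma-voom (0.14) and fry (0.19). The median was 0.06 with the stellate and fibroblast covariate (adjusted p = 0.84, the highest over the alternatives).

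Cell cycle genes rose as a group (camera adjusted p = 0.0019; adjusted p = 0.61 with an estimated correlation), with 28 of 34 tested genes higher, a median log2 fold change of 0.64, and 0 genes called over the list alone or over all genes. Mki67, a proliferation marker, was at 84.9 ± 35.0 CPM in chow and 159 ± 38.7 CPM in HFD, without overlap of the groups. Prc1 was at 2.49 ± 1.37 and 18.4 ± 23.5 CPM, Cenpf at 4.64 ± 2.38 and 19.7 ± 9.63 CPM, and the mitotic kinesin gene Kif11 at 1.71 ± 1.97 and 18.4 ± 19.3 CPM. The adjusted p of the list was 0.16 without HFD replicate 5, within a range of 4.4e-05 to 0.16 over the 8 libraries left out in turn. It was 0.098 with the filter at 5 CPM, and with the stellate and fibroblast covariate the list turned lower (adjusted p = 0.84).

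Cytosolic ribosomal protein genes fell as a group by a small amount (camera adjusted p = 0.00054; adjusted p = 0.64 with an estimated correlation). Of 77 tested genes 64 were lower and 13 higher, with a median log2 fold change of -0.29, and 0 were called over the list alone or over all genes. Rps4x was at 428 ± 84.8 CPM in chow and 313 ± 71.0 CPM in HFD, Rplp0 at 176 ± 39.2 and 117 ± 29.1 CPM, and Rps15 at 130 ± 32.7 and 87.6 ± 7.12 CPM. With the stellate and fibroblast covariate the median was -0.14 (adjusted p = 0.84, within a range of 2.8e-05 to 0.84 over the alternatives). The direction of this list and of the other 6 was the same under every scaling tried.

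Matrix remodelling genes rose as a group (camera adjusted p = 0.0019; adjusted p = 0.37 with an estimated correlation), with 13 of 16 tested genes higher, a median log2 fold change of 0.33, and 0 genes called over the list alone or over all genes. Tgm2, a transglutaminase gene, was at 3.42 ± 1.66 CPM in chow and 25.6 ± 18.4 CPM in HFD. The matrix protein genes Sparc, Bgn and Fn1 were at 6.81 ± 11.4, 7.95 ± 9.51 and 4.70 ± 7.03 CPM in chow and at 41.9 ± 36.2, 54.6 ± 36.9 and 53.4 ± 40.8 CPM in HFD, and Fn1 was at 0 CPM in HFD replicate 8. Beside this list, the summed transcripts of the stellate and fibroblast list were 512, 309, 256 and 106 CPM in HFD replicates 5 to 8 and 25.4 to 138 CPM in chow. Without HFD replicate 5 the adjusted p of the matrix list was 0.092, within a range of 2.4e-07 to 0.092 over the 8 libraries left out in turn. The median was 0.12 with the stellate and fibroblast covariate (adjusted p = 0.84, the highest over the alternatives). The call was kept with the stellate and fibroblast genes left out of the list (camera adjusted p = 0.0095), but that took out only Sparc. Fn1, Bgn and Tgm2 stayed in, so this decides nothing about stromal RNA.

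**Figure D2:**
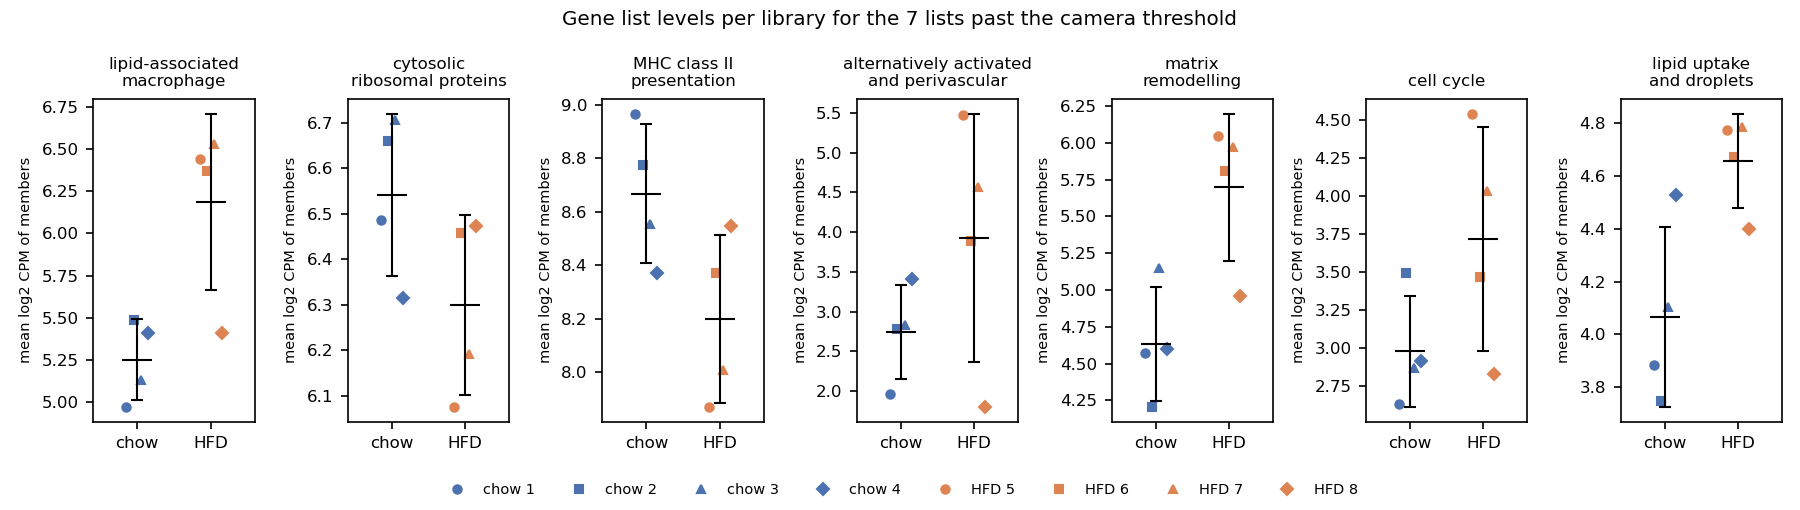
Mean log2 CPM of the tested genes of each of the 7 lists past the camera threshold, per library; points are libraries, horizontal bars the mean and whiskers the SD of 4 libraries per diet, and the axes do not start at 0. The lipid-associated macrophage list lies at 6.37 to 6.53 in 3 HFD libraries and at 5.41 in HFD replicate 8, beside 4.97 to 5.49 in chow.

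The other 28 pathway lists did not pass, with camera adjusted p-values of 0.30 to 0.94. Macrophage identity genes had a median log2 fold change of -0.08 over 24 tested genes (adjusted p = 0.41), with 0 called over the list alone. Interferon-stimulated genes had a median of 0.24 over 38 genes (adjusted p = 0.30), again with 0 called over the list alone. Without HFD replicate 6 this list passed (adjusted p = 0.0084), its mean log2 CPM being 4.39 in that library, 5.02 to 5.13 in the other HFD libraries and 4.20 to 4.77 in chow. Other lists that passed without 1 library were phagocytic and scavenger receptors (chow replicate 1, 0.031; HFD replicate 8, 0.0016; also 0.044 with no filter), immediate-early genes (chow replicate 4, 0.042; HFD replicate 6, 0.028) and leukocyte G-protein-coupled receptors (chow replicate 4, 0.042). The list of classical proinflammatory activation had a median of -0.15 and a mean of 0.20 over 19 genes, so these differ in sign (adjusted p = 0.90). Adjusted over the list alone 1 of its genes was higher, the interferon-induced chemokine gene Cxcl9, and 1 was lower, Il1b. Inflammasome genes had an adjusted p of 0.32, with Il1b the only gene lower when adjusted over the list alone. Lysosome genes had a median of 0.05 over 50 genes (adjusted p = 0.39), with 1 gene, Ctsd, higher when adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes had a median of -0.02 over 69 genes (adjusted p = 0.90) with 0 called over the list alone. None of these lists had a gene called over all genes tested.

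Transcripts of other cell types were compared to see whether the sorted fractions differed in what else they held. The insulin transcripts had similar means in both diets, Ins1 at 422 ± 153 CPM in chow and 432 ± 115 CPM in HFD, and Ins2 at 246 ± 88.2 and 247 ± 36.6 CPM. Iapp, the amylin gene, was at 46.2 ± 23.5 and 86.3 ± 22.6 CPM. Gcg, the glucagon gene, varied too much to compare, at 285 ± 287 and 377 ± 359 CPM. Acinar transcripts varied between libraries of the same diet, from 0.674 CPM in chow replicate 1 to 4508 CPM in chow replicate 4 and from 51.8 CPM in HFD replicate 8 to 2340 CPM in HFD replicate 7; the trypsin gene Prss2 was at 35.4 ± 56.8 and 21.4 ± 21.2 CPM. Stellate and fibroblast transcripts were at 83.9 ± 46.2 CPM in chow and 296 ± 168 CPM in HFD, a log2 difference of 1.83 (SD, n = 4; exact permutation p = 0.057, 0.46 after adjustment over the 16 lists). Of 20 genes in this list 17 had a higher level in HFD. The low sums were mostly Rgs5, a gene not higher in HFD. It held 78.8, 128 and 85.4 of the 81.0, 138 and 91.3 CPM in chow replicates 2, 3 and 4, and 0 in chow replicate 1. In HFD replicate 8 it held 97.0 of 106 CPM. In HFD replicates 5, 6 and 7 it held 31.2, 50.5 and 25.1 of 512, 309 and 256 CPM. Dendritic cell transcripts were at 932 ± 106 and 772 ± 67.7 CPM (exact permutation p = 0.057, adjusted p = 0.46). None of the 16 sums passed after adjustment (adjusted p = 0.46 to 1), and no single sum could, the smallest adjusted p for 1 alone being 0.46.

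With camera, 0 of the 7 cell type lists with enough tested genes passed. The beta cell list (11 tested genes) and the alpha cell list (8) each had an adjusted p of 0.070 towards higher levels in HFD (adjusted p = 0.29 with an estimated correlation). The mean log2 CPM of the beta cell list was 4.12 to 4.71 in the HFD libraries and 3.31 to 3.83 in chow (exact permutation p = 0.029, adjusted p = 0.20). Both lists passed without chow replicate 2 (adjusted p = 0.047 for beta and 0.011 for alpha) and without HFD replicate 5 (0.049 and 0.036), as did the pan-endocrine list without chow replicate 2 (0.017). The acinar list passed as lower in HFD without chow replicate 1 (0.0010) and without chow replicate 2 (0.0022). Those 2 libraries held 0.674 and 2.97 CPM of acinar transcripts, against 2186 and 4508 CPM in chow replicates 3 and 4. The correlation estimated between genes of this list was 0.92, far above the preset 0.01, so these passes decide nothing. With it the adjusted p over all libraries was 0.98. In the beta cell list G6pc2 was called when adjusted over the list alone, with a log2 fold change of 3.23 (SE 0.96), and 0 genes over all genes; Iapp had one of 0.90 (SE 0.45), Ucn3 one of 3.07 (SE 1.63) and Ero1lb one of -0.65 (SE 0.37). In the alpha cell list Pcsk2 had a log2 fold change of 2.15 (SE 0.73), Peg3 of 0.90 (SE 0.41), Slc7a2 of 1.03 (SE 1.27) and Ttr of -0.64 (SE 1.12), with 0 called over the list alone. With 1 library left out, the log2 fold change ranged from 1.80 to 5.32 for Ucn3 and from 0.26 to 3.68 for Slc7a2. It ranged from -0.82 to -0.12 for Ero1lb and from -1.16 to -0.096 for Ttr. The stellate and fibroblast list had 3 tested genes, Sparc, Pdgfrb and Rgs5, too few for camera. It passed as higher in HFD without a filter (adjusted p = 8.6e-13), without chow replicate 1, 2, 3 or 4 (4.6e-12, 2.8e-12, 2.7e-14 and 2.4e-13) and without HFD replicate 8 (4.6e-28). With 1 library left out the filter asks for fewer libraries. Collagen genes with no or few counts in chow were then kept only through HFD replicates 5, 6 and 7. Their direction was set by that, so the passes without 1 library are no separate support. All these passes used the preset correlation of 0.01 between genes. The stellate and fibroblast list also passed when lists with at least 3 tested genes were allowed, a choice made after seeing the data (adjusted p = 0.019). It was not testable without HFD replicate 5, 6 or 7.

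**Figure D3:**
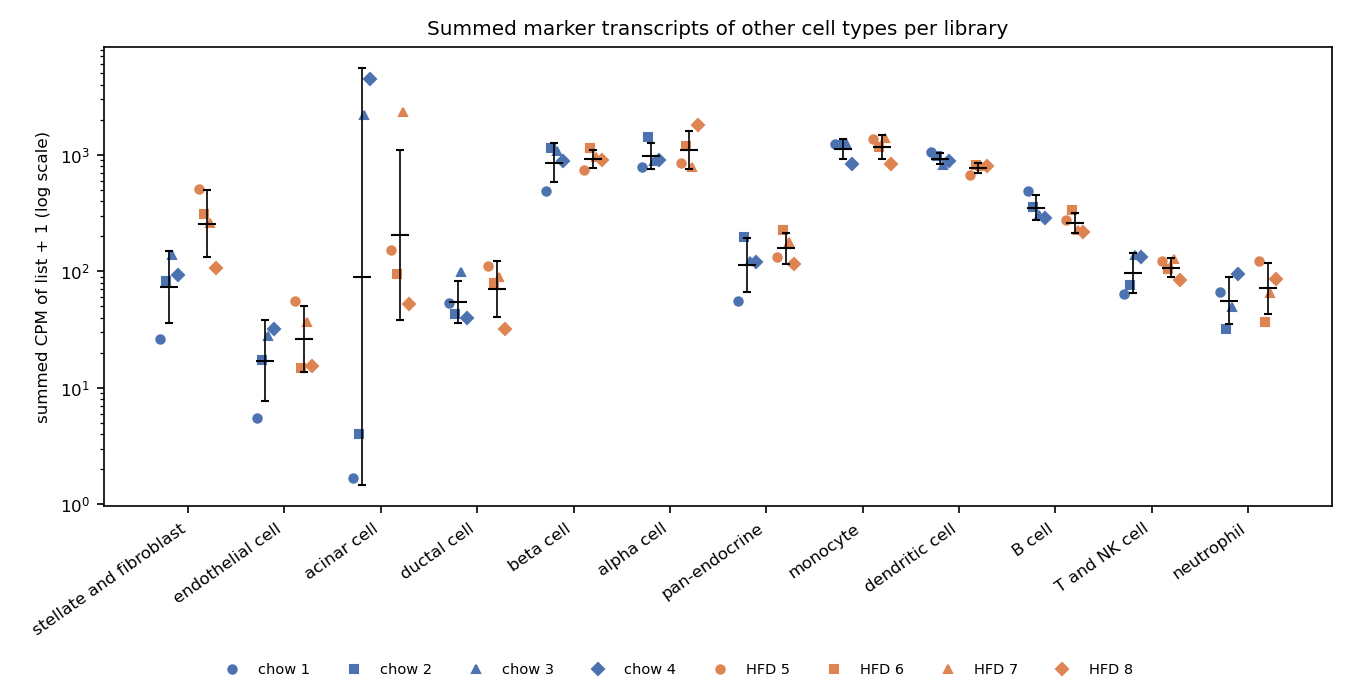
Summed CPM plus 1 of marker transcripts of 12 other cell types per library on a log axis; points are libraries, horizontal bars the mean and whiskers the SD on the log2 scale of 4 libraries per diet. The stellate and fibroblast sum lies at 256 to 512 CPM in HFD replicates 5, 6 and 7 and at 106 CPM in HFD replicate 8, against 25.4 to 138 CPM in chow, and acinar transcripts span 0.674 to 4508 CPM.

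Measures of library quality were compared by exact permutation, where no single measure could pass over 5, since the smallest adjusted p for 1 alone is 0.14. The number of genes with at least 1 count was 12510 ± 537 in chow and 13120 ± 228 in HFD (SD, n = 4; exact permutation p = 0.086, 0.29 after adjustment over 5 measures). Mitochondrially encoded genes took 24.99% ± 1.55 and 24.99% ± 2.43 of the counts, most of it the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 at 21.5% ± 1.52 and 21.4% ± 1.78. Ribosomal protein genes took 0.947% ± 0.086 in chow and 0.834% ± 0.054 in HFD (exact permutation p = 0.11, adjusted p = 0.29). The 50 most abundant genes took 39.6% ± 1.14 and 37.7% ± 3.15. Xist was at 0 to 2.98 CPM and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together at 347 to 459 CPM, as male mice give.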

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

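The tests of stellate and fibroblast transcripts, the covariate made from them and the test of single libraries for MHC class II were chosen after the results were seen. Among 182 groups of 4 libraries examined, 6 held a library far from the other libraries of its diet, and chance gives about 1 in 20. HFD replicate 8 had a mean log2 CPM of 5.41 for the lipid-associated macrophage list, below 6.37 to 6.53 in the other HFD libraries. It also had 0 CPM of Fn1, against 45.2 to 93.6 CPM. Chow replicate 4 had 837 CPM of monocyte list transcripts against 1204 to 1262 CPM, and HFD replicate 5 had 672 CPM of dendritic cell transcripts against 794 to 821 CPM. Pdgfrb was at 2.49 CPM in chow replicate 3 and at 0 CPM in the other chow libraries. Rgs5, a pericyte gene, was at 0 CPM in chow replicate 1 and at 78.8 to 128 CPM in the other chow libraries.

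Macrophage lists that moved with HFD were the lipid-associated list (higher), the alternatively activated and perivascular list (higher) and MHC class II presentation (lower), all lost with an estimated correlation (adjusted p = 0.37, 0.61 and 0.61) and with the stellate and fibroblast covariate (0.84, 0.18 and 0.98), which turned the alternatively activated list lower. Losses with that covariate decide little, since it leaves mostly HFD replicate 8 to set against chow. Of the 35 splits of the 8 libraries into 4 and 4, 2 gave as many called lists as the diet split, whose 7 lists were equalled by the highest other split, so chance is not excluded for the count of lists. At the preset correlation camera kept the lipid-associated list without any single library, with a highest adjusted p of 0.00028. MHC class II was kept only narrowly, with a highest camera adjusted p of 0.048 without HFD replicate 5. The correlation estimated between class II genes was 0.27, so this cannot exclude that HFD replicate 5 carried that call. The alternatively activated list reached 0.18 without HFD replicate 5, so its call was lost without that library. Its mean log2 CPM also lay above the chow range of 1.97 to 3.41 in HFD replicates 6 and 7, at 3.89 and 4.56. The lipid uptake, cell cycle and matrix calls were lost without HFD replicate 5 too (camera adjusted p = 0.11, 0.16 and 0.092). Dilution of macrophage transcripts by endocrine and acinar RNA is argued against for MHC class II, as far as the genes of those lists show. They took 0.215% to 0.457% of the counts in the HFD libraries and 0.140% to 0.644% in chow. This share leaves out all other RNA of those cells, so it is a lower bound. A different mix of macrophages, stromal material in HFD replicates 5, 6 and 7, and a change within the cells through diet all stay open. Fewer dendritic or B cells stay open too. The sums and median log2 fold changes of those lists were lower in HFD, without a call, but their mean log2 CPM was higher.

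Stellate and fibroblast transcripts, among them collagen genes with no count in chow, had a higher sum in HFD. The sum did not pass an exact permutation test that could not call 1 sum alone (p = 0.057, adjusted p = 0.46). The list passed camera without a filter (adjusted p = 8.6e-13), but at the preset correlation, which treats its genes as nearly independent. Its mean log2 CPM separated the diets (exact permutation p = 0.029, not adjusted), but only just. It was -0.87 to -0.40 in chow, -0.38 in HFD replicate 8, and 2.7, 2.12 and 1.855 in HFD replicates 5, 6 and 7. The sum of HFD replicate 8 lay within the chow range, with 97.0 of its 106 CPM from Rgs5. Of the 20 list genes 17 had a higher level in HFD, but this restates the sum, some of them by a few counts, so it cannot tell whether RNA of stromal cells is the source. The stellate and fibroblast covariate is this mean log2 CPM and shares 0.637 of its variance with diet. A diet difference fitted with it rests largely on HFD replicate 8 against chow, so the changes below do not show that stromal RNA is the source. With it the log2 fold change of Igf1 went from 3.07 (SE 0.51) to 0.54 (SE 0.56). Il1b went from -1.51 (SE 0.35) to -0.78 (SE 0.54), Cd36 from 0.95 (SE 0.24) to 0.40 (SE 0.37) and Plin2 from 1.16 (SE 0.34) to 0.92 (SE 0.50). Itgb8 went from -1.18 (SE 0.23) to -1.34 (SE 0.39) and Cdk6 from -0.66 (SE 0.13) to -0.72 (SE 0.22). One library alone does not carry the difference, as the log2 difference of the sums was still at least 1.49 without any 1 HFD library. Whether macrophages themselves held these transcripts, and whether diet or dissection brought more stroma, stays open.

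Ribosomal protein genes were lower in HFD by a median log2 fold change of -0.29, a call lost with an estimated correlation (adjusted p = 0.64) and with the stellate and fibroblast covariate (0.84). Among 10000 gene sets matched on transcript length and expression this median lay at percentile 0.73, and among sets matched on GC content and expression at percentile 0, both outside the central 95%. The length-matched sets were themselves lower, with a median of -0.14 (central 95% -0.25 to -0.007) against -0.021 over all tested genes, so length may account for part of the fall. The GC-matched sets had a median of -0.05. Random sets lack the correlation estimated between ribosomal protein genes (0.17), so their spread may be too narrow for these percentiles to exclude either bias. At the preset correlation camera kept the call without any single library, but only narrowly, with a highest adjusted p of 0.048 without HFD replicate 5. This cannot exclude that HFD replicate 5 carried it. Reads shared with ribosomal protein pseudogenes and a difference between the sorted cells stay open and were not tested.

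For single genes, all 35 of 35 splits gave at least as many called genes as the diet split, which had to be so with 0 called and decides nothing about chance; the highest other split had 3. The 542 genes with an unadjusted p under 0.05 in the diet split were reached by 1 of the 35 splits, the diet split itself, and the highest other split gave 502. The other splits ranged from 319 to 502, so a chance split of the libraries is argued against for this count, although 1 of 35 is the smallest share that these splits can give.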

How the results depend on the processing

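Several alternatives, named here as such, were chosen after seeing the data: the stellate and fibroblast covariate, list means per library, lists with at least 3 tested genes, and lists without stellate and fibroblast genes. The edgeR count of 0 genes became 92 with DESeq2 (62 higher, 30 lower; 21 had no count in chow, and 59 were tested in edgeR), 45 without a filter (26 higher, 19 lower), 1 with limma-voom quality weights and 1 at adjusted p under 0.10; leaving out 1 library gave 0 to 11, the 11 without HFD replicate 8. It was 0 under every other alternative. The count of 7 pathway lists became 0 with an estimated correlation, with fry (6 with its mixed test, which ignores direction), with the stellate and fibroblast covariate, and with list means per library, where the exact test could not call a single list (smallest adjusted p for 1 alone 1); leaving out 1 library gave 3 to 9, the 3 without HFD replicate 5. The 0 called cell type lists became 1 without a filter (stellate and fibroblast), 1 with the acinar covariate (the acinar list itself, adjusted for its own genes, so this decides nothing) and 1 with at least 3 tested genes, and 0 to 5 with 1 library left out, when the filter also keeps more genes (the stellate and fibroblast list in 5 of 8). The filter at 5 CPM ended the lipid uptake and cell cycle calls (camera adjusted p = 0.12 and 0.098). The lipid uptake call also ended with the pan-endocrine covariate, the surrogate variable and limma-voom. Without a filter the phagocytic and scavenger receptor list passed as well (camera adjusted p = 0.044). All 7 pathway calls were kept with stellate and fibroblast genes left out of the lists. Of the called lists only matrix remodelling holds such a gene, Sparc. The other called lists lost no gene, so this does not test them for stromal RNA. Cell type sums and library measures stayed at 0 calls, which their exact test largely fixes: 1 sum alone cannot go below an adjusted p of 0.46 and 1 measure alone below 0.14. With the stellate and fibroblast covariate, which moves with diet, 2 lists turned direction, alternatively activated (adjusted p = 0.18) and cell cycle (0.84). The same covariate gave log2 fold changes of -0.68 for Itgam, 0.035 for Csf1r, -0.40 for Mrc1, -0.62 for Cd9, -0.032 for Ins2, 0.20 for Cd74, -5.46 for Cbr2, -3.68 for Cd209a, -0.77 for Sparc, -0.21 for Bgn, -5.99 for Fn1, -5.01 for Kif11, -0.48 for Pdgfrb and 0.21 for Rgs5, all opposite to the values without it. Further turns, all in genes not past the threshold, were Cd68 at 0.038 with library totals, 0.083 with the pan-endocrine covariate, 0.02 with the surrogate variable and 0.072 with limma-voom; Ins1 and Ins2 at -0.13 and -0.15 (pan-endocrine) and -0.12 and -0.15 (surrogate variable); Ins2, Prss2 and Rgs5 at -0.005, 1.90 and 0.62 (limma-voom); and Gcg, Prss2, Cela2a, Klk1, Sycn and Cela1 at -0.079, 3.77, 1.26, 2.28, 0.71 and 0.077 (acinar covariate). With 1 library left out, log2 fold changes ranged from -0.17 to 0.055 for Cd68, -0.14 to 0.003 for Csf1r, -0.42 to 1.29 for Gcg, -0.17 to 0.25 for Ins1, -0.21 to 0.20 for Ins2, -0.017 to 0.30 for Itgam, -1.46 to 1.497 for Prss2, -3.57 to 0.08 for Sycn and -0.40 to 0.51 for Trem2. Sparc, Pdgfrb and Rgs5 belong to the stellate and fibroblast list, and Prss2, Cela2a, Klk1, Sycn and Cela1 to the acinar list. With the covariate made from their own list they are adjusted for themselves, so those turns decide nothing. The cause of the other changes was not tested. The other alternatives kept the direction of the 65 named genes tested. No paired analysis was possible because the diets share no replicate numbers.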

Other observations

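Collagen and other matrix transcripts, chosen after their values were seen, were nearly confined to HFD replicates 5, 6 and 7. Col1a1 (chromosome 11, 94936224 to 94953042), a fibrillar collagen gene, had 0 counts in chow and 749 in HFD, at least 242-fold higher against a floor of 3 counts over the chow group, with 72.5, 41.2 and 30.8 CPM in HFD replicates 5, 6 and 7 and 0.201 CPM in HFD replicate 8. Col1a2 had 9 counts in chow and 865 in HFD (DESeq2 log2 fold change 6.47, SE 1.05, adjusted p = 4.0e-06), and Col3a1 9 and 1292 (DESeq2 adjusted p = 0.035). Dcn and Lum, small matrix proteoglycan genes, had 0 counts in chow and 135 and 195 in HFD, and the microfibril gene Fbn1 0 and 207. The edgeR filter removed these genes, since too few libraries reached its minimum count. Gas6, a ligand of the receptor Mertk and a gene of the alternatively activated list, had 1 count in chow and 420 in HFD, with 50.3, 16.0 and 14.3 CPM in HFD replicates 5, 6 and 7 and 1.41 CPM in HFD replicate 8. Not every stellate list gene followed: Rgs5 was at 74.6 CPM over the chow libraries and 51.2 CPM over the HFD libraries, Cspg4 had 24 counts in chow and 1 in HFD, and the smooth muscle gene Acta2 had 0 in chow and 8 in HFD, all in HFD replicate 8.

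Further genes chosen after their values were seen included Ahnak, which like Lyz1 followed the collagen genes across the HFD libraries and whose cell of origin was not tested, at 42.5 to 83.8 CPM in chow, 524, 391 and 729 CPM in HFD replicates 5, 6 and 7, and 39.8 CPM in HFD replicate 8 (DESeq2 log2 fold change 2.70, SE 0.75, adjusted p = 0.045). Lyz1, a lysozyme gene with a near-identical partner in Lyz2, had 24.0, 18.4 and 131 CPM in HFD replicates 5, 6 and 7, 0 CPM in HFD replicate 8 and 0 to 1.24 CPM in chow (DESeq2 adjusted p = 0.059). The efferocytosis receptor gene Mertk was at 18.2 to 84.5 CPM in chow and 62.4 to 209 CPM in HFD (DESeq2 adjusted p = 0.086). The cytokine gene Osm had 4 counts in chow and 201 in HFD, with its highest level, 20.3 CPM, in HFD replicate 8 (DESeq2 adjusted p = 0.0038). Cxcl9 was at 0.944 to 19.5 CPM in chow and 24.0 to 141 CPM in HFD (DESeq2 adjusted p = 0.029).

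The gene models AY036118, CT010467.1 and Gm37376 together took 2.92% ± 0.629 of the counts in chow and 1.99% ± 0.523 in HFD (SD, n = 4; exact permutation p = 0.057).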
